A study of Mus musculus with 8 samples.

How the data were processed

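Genome-wide 5-hydroxymethylcytosine (5hmC) was profiled in 8 mouse samples. 5hmC is the oxidised form of 5-methylcytosine that the TET enzymes produce. Per the labels' protocols, sonicated genomic DNA was glucosylated at 5hmC with an azide-bearing sugar by beta-glucosyltransferase, biotinylated through a cleavable linker, captured on streptavidin beads, released with DTT and made into Illumina libraries. Samples were grouped by their titles and cell type labels into fibroblasts (MEF), intermediates of the OSNK and OySyNyK methods at D1, D3 and D5, and induced pluripotent stem cells (iPSC), with 1 library in each group. D is read as day. What the factor names stand for is background knowledge of the study and not from the labels.

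The deposited files are peak lists, 1 per library, so peaks were called per sample and not on pooled samples. Bowtie and MACS are named per the submitters' processing notes; their versions, settings and any control library are not given in the sources used here. Each peak has a score as deposited, which in MACS is -10 times the log10 of the peak's p-value. The lowest score in every list was 50, which corresponds to a p-value of 1e-05. Read counts per library were not used here, so sequencing depth is unknown, and the number of peaks depends on depth and enrichment as well as on 5hmC. Peaks did not overlap within a list.

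The builds named per the submitters' processing notes are hg18 and NCBI36, which are human. The peak lists hold chromosomes 1 to 19 and X, as in mouse. Peaks extended beyond the last gene of the mouse assembly GRCm38 on 10 of 20 chromosomes, and chromosome 1 had peaks up to position 197168143. The lists are therefore in a mouse assembly other than GRCm38; from general knowledge of chromosome lengths, mm9 is the assembly they match. Coordinates are given as in the lists, counted from 1. No annotation of that assembly was used here, so peaks were not assigned to genes. The planned shares of promoters, exons and introns, the planned gene lists and the planned named genes were left out for that reason. Regions of 100 kb took the place of genes, as laid down before the data were examined.

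Overlap was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and checked against bedtools 2.31.1, which gave the same counts for all 64 ordered pairs of libraries. A peak was overlapped when it shared at least 1 bp with a peak of the other list. iPSC peaks without a MEF peak are called iPSC-gained, MEF peaks without an iPSC peak are called MEF-only, and MEF peaks with an iPSC peak are called shared. For the order over days, the peaks of all libraries were merged into regions, each scored as present or absent in MEF, D1, D3, D5 and iPSC. Counts of regions gained or lost in order, without reappearance, were a summary chosen after seeing the data. Shares of peaks have exact (Clopper-Pearson) 95% intervals. Differences between libraries over the same peaks have 95% intervals from 1000 resamplings of 10-Mb blocks of the genome. Both cover counting error along the genome only and not the variation between cultures, which 1 library per group cannot give. No p-value is given for any comparison; an exact sign-flip test over the 3 days could not go below p = 0.25 (two-sided). The overlap given by list length and peak width was estimated from 100 circular shifts, in which all peaks of a chromosome were moved by 1 random offset. Such shifts do not keep regions dense in peaks in place. A ratio to the shifted value therefore mixes shared dense regions with shared single peaks. On simulated lists carrying 20% and 30% of the 43001 iPSC-gained peaks plus randomly placed peaks, the recovered shares were 23.3% and 32.7%, against 23.2% and 32.8% expected with chance overlap.

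The regions named in the text were chosen by a rule set before the data were examined: the 5 regions of 100 kb with the largest rise and the 5 with the largest fall in peak-covered length from MEF to iPSC, and the 5 in each direction whose OySyNyK minus OSNK difference had the same sign on all 3 days and the largest smallest value. Alternatives set beforehand were an overlap of at least 50% of the peak, a score of at least 100, equal numbers of peaks (the 54938 best-scoring of each library, the size of the smallest list), peaks within 1 kb merged, and autosomes only. The last was run for peak numbers and covered length, and X held 0.841% of the peaks or less in every list. Peaks of 500 bp round their midpoints, with all peaks or equal numbers, leaving out chromosomes 12, 13, 16, 18 and X, and leaving out also 5, 6, 11 and 17, the other autosomes whose iPSC to MEF ratio lay outside the range of the intermediates, were added after seeing the data. So were all alternatives for X shares, chromosome ratios and regions gained or lost in order. Figures were drawn with matplotlib 3.10.9.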

Results

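5hmC peak lists were compared for mouse embryonic fibroblasts (MEF), the starting cells, for cells on their way to pluripotency at D1, D3 and D5, and for induced pluripotent stem cells (iPSC). The intermediates were made with OSNK, known from the study as the reprogramming factors Oct4, Sox2, Nanog and Klf4, or with OySyNyK, in which the first 3 of these are fused to a transactivation domain of YAP. The title of the iPSC sample names the OySyNyK factors. The question set by the design was how 5hmC progresses under each method. The lists held 684512 peaks in all. MEF had 65776 peaks covering 63.0 Mb. OSNK had 116302, 89497 and 92762 peaks at D1, D3 and D5, covering 91.9, 98.2 and 70.2 Mb. OySyNyK had 100951, 93694 and 70592 peaks, covering 76.9, 74.3 and 57.6 Mb. iPSC had the fewest, 54938 peaks covering 41.1 Mb. Median peak width lay between 641 bp in iPSC and 911 bp in OSNK D3. Median peak score, the authors' value for each peak, was 103 in MEF and 71.0 in iPSC. It was 105, 91.4 and 81.3 at D1, D3 and D5 of OSNK and 95.8, 84.2 and 75.8 at those of OySyNyK. Every group had 1 library and no replicate, and depth was unknown, so list lengths are descriptive.

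The first comparison set the start against the end of reprogramming. Most 5hmC peaks of MEF had no overlapping peak in the iPSC list. That list was the shortest and had the lowest median score, so a missing peak need not mean missing 5hmC. Of the 65776 MEF peaks, 54329 were MEF-only, which is 82.6% (95% interval 82.3 to 82.9), and 11447 were shared. Of the 54938 iPSC peaks, 43001 were iPSC-gained, which is 78.3% (95% interval 77.9 to 78.6). The other 21.7% of iPSC peaks overlapped a MEF peak, 4.81 times the 4.51% ± 0.24 (SD, n = 100 shifts) obtained when the MEF peaks were shifted along their chromosomes. Across 26363 regions of 100 kb, peak cover was lower in iPSC than in MEF in 12148 and higher in 5150. The correlation of MEF and iPSC cover over these regions, which are not independent replicates, was 0.58 (Pearson's r) and 0.65 (Spearman's rho).

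Regions are given in the coordinates of the lists' own mouse assembly and were not assigned to genes. The regions with the largest falls went from broad 5hmC cover in MEF to little in iPSC. On chromosome 10, positions 119800001 to 119900000 were covered to 48.2% in MEF and 8.86% in iPSC. On chromosome 8, positions 11300001 to 11400000 were covered to 40.6% and 2.18%. The other 3 regions of this kind began at 31000001 on chromosome 6, 63500001 on chromosome 9 and 92900001 on chromosome 1, and fell by 34.5, 32.7 and 32.6 percentage points. MEF cover of all 5 lay between 37.8% and 48.2%. At OSNK D3, the list with the widest peaks, cover was above MEF in each, between 45.5% and 70.0%. At OySyNyK D3 it was above MEF on chromosomes 10, 6 and 1 only. Cover at OSNK D5 lay between 35.0% and 53.2%, above MEF except on chromosome 8, and at OySyNyK D5 between 29.1% and 40.1%, below MEF in each. The lists differed in the sequence they covered, with 63.0 Mb in MEF and 98.2 Mb at OSNK D3. Whether the falls from MEF to iPSC were steady over the days therefore cannot be told from these values. The largest rise was on chromosome 11 at positions 117900001 to 118000000, from 7.50% in MEF to 39.9% in iPSC. On chromosome 5, positions 116000001 to 116100000 rose from 8.62% to 36.0%. The other 3 largest rises were on chromosome 12, in the regions starting at 111800001, 112500001 and 103800001, with gains of 31.1, 29.2 and 24.6 percentage points. With a score of at least 100, the falls on chromosomes 8 and 1 were smaller, at -24.2 and -20.3 percentage points. Chromosome 12 as a whole had 1.75 times the iPSC to MEF peak ratio of the median autosome.

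**Figure D1:**
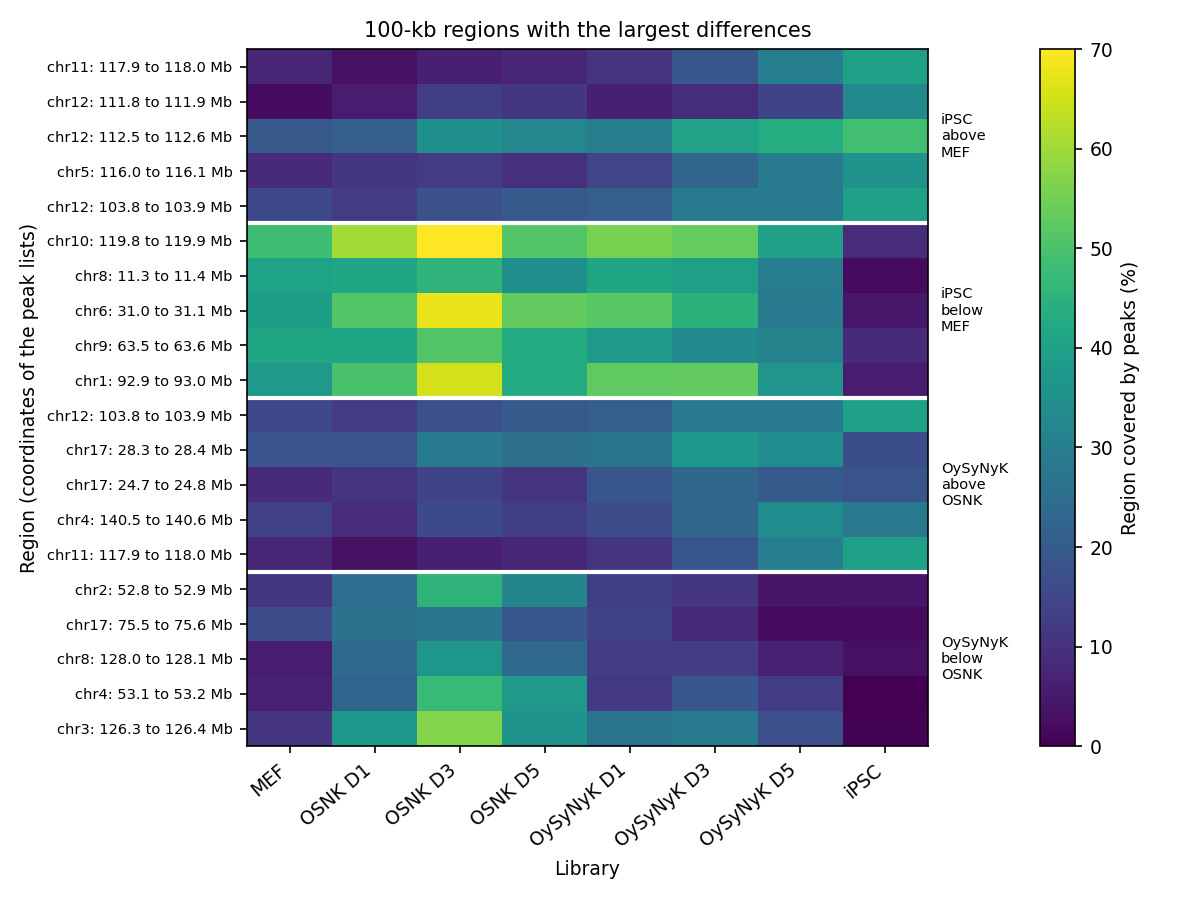
Percent of each named 100-kb region covered by 5hmC peaks (colour) in the 8 libraries (columns), for the 5 regions with the largest values in each of 4 directions (row blocks); regions chosen by 2 rules appear in both blocks. The top block is brightest in iPSC, with OySyNyK above OSNK at D5, and the bottom block is brightest in OSNK D3, reaching 57.1%.

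The second comparison followed each method over time. The share of iPSC-gained peaks overlapped rose from day to day with both methods. With OSNK, 11.5% of the 43001 iPSC-gained peaks were overlapped at D1 (95% interval 11.2 to 11.8), 18.9% at D3 (18.5 to 19.2) and 22.0% at D5 (21.7 to 22.4). With OySyNyK the shares were 14.9% (14.5 to 15.2), 25.4% (24.9 to 25.8) and 30.2% (29.8 to 30.7). Shifted peaks gave 4.52% to 6.85%, so that the ratio to the shifted value went from 1.68 to 4.06 with OSNK and from 2.51 to 6.70 with OySyNyK. By definition, peaks of an intermediate that overlap MEF peaks can hardly overlap iPSC-gained peaks, while shifted peaks can. Such peaks made up 43.8% at OSNK D1 and 31.2% at OSNK D5, and 48.6% and 35.5% with OySyNyK. Part of the rise of the ratio may follow from this. From D1 to D5 the share of iPSC-gained peaks overlapped rose by 10.5 percentage points with OSNK (95% interval 10.0 to 11.1) and by 15.4 with OySyNyK (14.7 to 16.05). Peaks that had appeared were mostly found again: 81.1% of those present at OSNK D1 and 83.7% of those present at OySyNyK D1 were present at D3, against 10.8% and 15.2% of those absent at D1. From D3 to D5 these values were 77.8% and 74.7%, against 9.08% and 15.2%. Not all peaks kept to this order, and 2.96% with OSNK and 4.36% with OySyNyK were overlapped at D3 only. Even so, 56.3% of the iPSC-gained peaks were overlapped in none of the 6 intermediates (95% interval 55.8 to 56.8). With equal numbers of peaks the shares were lower, 5.89%, 13.7% and 15.9% with OSNK and 9.07%, 17.7% and 26.1% with OySyNyK. With equal numbers of 500-bp peaks they were 5.14%, 10.4% and 14.7%, and 8.37%, 16.2% and 24.7%.

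The share of MEF-only peaks still present went down from day to day with both methods. With OSNK, 74.8% of the 54329 MEF-only peaks were overlapped at D1 (95% interval 74.4 to 75.2), 47.2% at D3 and 36.4% at D5. With OySyNyK the shares were 69.2% (68.8 to 69.6), 44.2% and 28.8%. Peaks present at D1 and absent at D3 and D5 made up 26.7% with OSNK and 25.8% with OySyNyK, and peaks present until D3 and absent at D5 made up 14.3% and 17.1%. A peak absent on one day and present on a later one was seen for 7.46% and 7.63%. Of the peaks shared by MEF and iPSC, 64.6% were overlapped at D5 with OSNK and 72.0% with OySyNyK, and 53.0% and 58.1% were overlapped on all 3 days. From D1 to D5 the shared peaks fell by 8.25 percentage points with OSNK (95% interval -9.39 to -7.07) and by 4.35 with OySyNyK (-5.53 to -3.23). Over the alternatives these changes were between -14.1 and -3.97 with OSNK and between -8.54 and 0.865 with OySyNyK, and the latter was above 0 in 3 of them, as with equal numbers of peaks (0.747, 95% interval -0.68 to 2.17). MEF-only shares at D3 and D5 were 31.1% and 23.7% with OSNK with equal numbers of 500-bp peaks, and 19.1% at OySyNyK D5 with a score of at least 100.

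**Figure D2:**
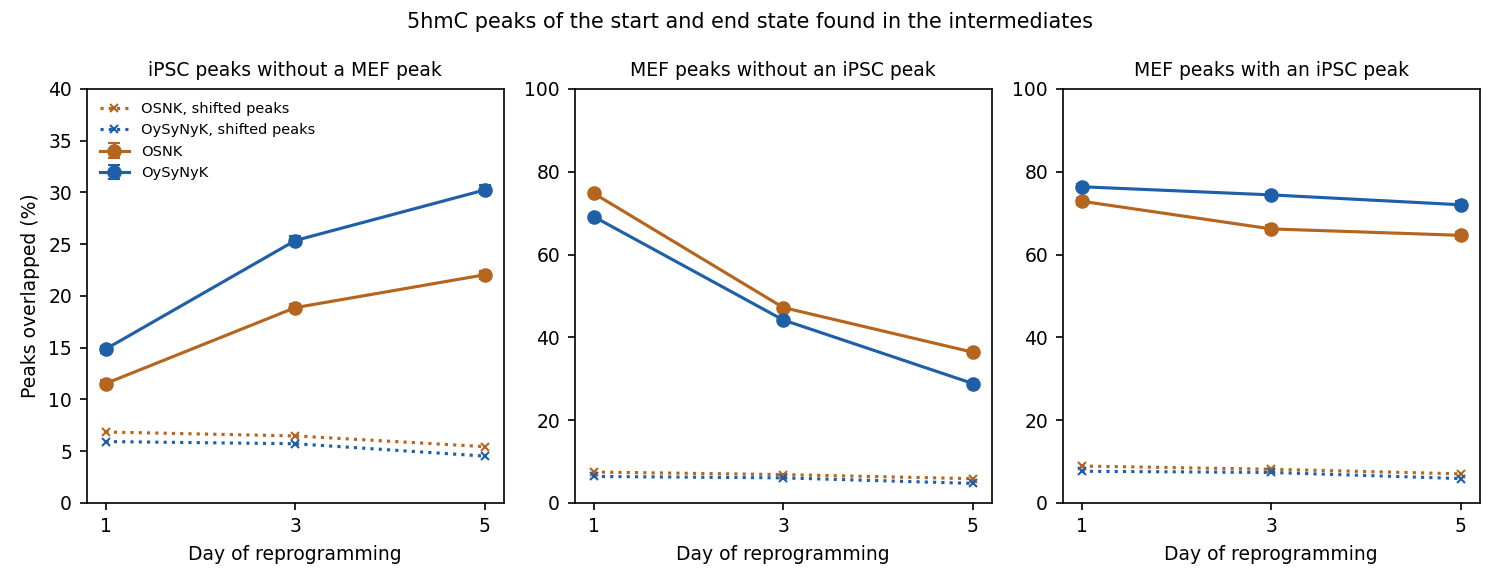
Percent of iPSC-gained peaks (left, axis to 40%), MEF-only peaks (middle) and peaks shared by MEF and iPSC (right, both axes to 100%) overlapped by a peak of each intermediate, against the day. Points are single libraries with exact 95% intervals, mostly smaller than the symbols, and crosses with dotted lines are means of 100 circular shifts; OySyNyK ends at 30.2% of iPSC-gained peaks and OSNK at 22.0%.

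The libraries of all groups together marked 222732 separate regions, which were followed from MEF through the days to iPSC. Regions gained in order, which were absent in MEF, present from one of the days onward and present in iPSC, numbered 8320 with OSNK and 11458 with OySyNyK. Regions lost in order, which were present in MEF and at D1, absent in iPSC and not found again once absent, numbered 36008 with OSNK and 33671 with OySyNyK. Of these, 15345 with OSNK and 12040 with OySyNyK were still present on all 3 days and absent only in iPSC. Those present until D3 and absent at D5 numbered 6683 and 8489, and those absent from D3 on numbered 13980 and 13142. The larger OSNK total therefore does not mean more loss by D5. With OSNK, 6604 regions were present in MEF, on all 3 days and in iPSC, and with OySyNyK 7147 were. Regions in neither MEF nor iPSC but present on at least 1 day made up 41.1% with OSNK (95% interval 40.9 to 41.3) and 32.8% with OySyNyK (32.6 to 33.0). With a score of at least 100, regions gained in order numbered 1608 and 2478 and regions lost in order 21501 and 19153, and with equal numbers of peaks regions lost in order numbered 22213 and 21176.

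Strong peaks and weak peaks differed in their shares. Of the 10750 highest-scoring iPSC-gained peaks, 45.6% were overlapped at OySyNyK D5 (95% interval 44.7 to 46.6) and 27.6% at OSNK D5 (26.8 to 28.5). Of the 10751 lowest-scoring ones, 21.3% and 18.9% were overlapped. Among MEF-only peaks, the 13582 highest-scoring were almost all still present at D1, 96.3% with OSNK and 93.7% with OySyNyK, and 51.1% and 41.9% were present at D5. The OSNK value was 33.7% with equal numbers of 500-bp peaks.

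The third comparison set the methods side by side on the same day. OySyNyK overlapped more iPSC-gained peaks than OSNK on each day, by 3.33 percentage points at D1 (95% interval 2.82 to 3.82), 6.49 at D3 (5.77 to 7.24) and 8.20 at D5 (7.29 to 9.02). Among iPSC-gained peaks found with 1 method only, OySyNyK held 65.8% at D1, 68.9% at D3 and 69.3% at D5. OySyNyK overlapped fewer MEF-only peaks, with differences of -5.63 percentage points at D1 (95% interval -6.21 to -5.08), -3.01 at D3 (-3.75 to -2.30) and -7.57 at D5 (-8.13 to -7.01). It overlapped more of the shared peaks, by 3.49, 8.22 and 7.39 percentage points, with a range of 2.90 to 12.8 over all days and alternatives. With equal numbers of peaks the iPSC-gained differences were 3.18, 3.97 and 10.3, and the MEF-only differences were -1.58, -4.30 and -1.88. Over all alternatives the latter lay between -8.56 and -0.745 at D1, -6.48 and 0.0944 at D3, and -7.71 and -1.17 at D5. With peaks of 500 bp the MEF-only difference at D3 was 0.0944 (95% interval -0.64 to 0.83), and OSNK D3 was the list with the widest peaks. The OSNK lists covered more sequence on each day, which favours overlap with MEF-only peaks. Its part in the MEF-only differences was not separated.

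The overlap of the methods was smaller at D3 and D5 than at D1. The bases covered by both methods were 47.8% of those covered by either at D1, 38.0% at D3 and 33.0% at D5. They were 35.8%, 23.8% and 23.7% with equal numbers of 500-bp peaks. Peaks called with 1 method and not the other differed in where they fell. Of the 25050 OySyNyK-specific peaks at D1, 15.5% overlapped an iPSC peak (95% interval 15.1 to 15.98), against 4.69% of the 41869 OSNK-specific peaks (4.49 to 4.89). At D3 the shares were 18.8% and 6.71%. At D5 they were 28.8% of 27419 (28.3 to 29.4) and 7.43% of 49454 (7.20 to 7.66). MEF overlap of the same peaks was closer, at 22.3% for OySyNyK-specific and 19.9% for OSNK-specific peaks at D5. With a score of at least 100, the iPSC overlap was 8.41% and 1.35% at D1, 11.6% and 2.34% at D3 and 21.8% and 3.34% at D5, for OySyNyK-specific and OSNK-specific peaks.

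**Figure D3:**
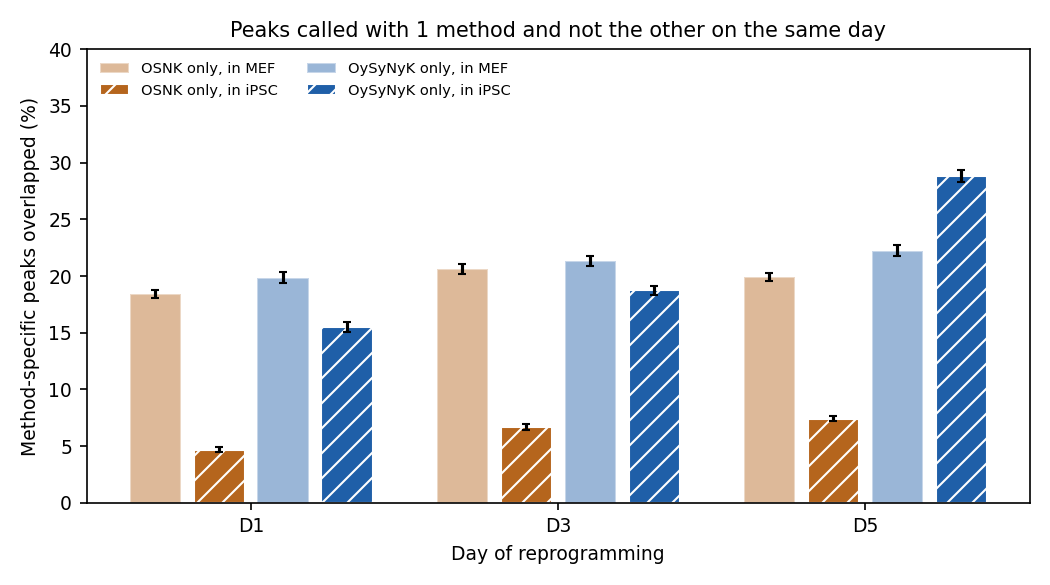
Percent of method-specific peaks (called with 1 method and not with the other on that day) that overlap a MEF peak (pale bars) or an iPSC peak (hatched bars), by day, with exact 95% intervals over peaks. The iPSC overlap of OySyNyK-specific peaks goes from 15.5% to 28.8%, and that of OSNK-specific peaks from 4.69% to 7.43%.

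Regions in which OySyNyK exceeded OSNK on all 3 days were fewer, 1568, than those in which it lay below, 7090, and the OSNK lists covered more sequence on each day. In the former, iPSC cover exceeded MEF cover by 1.21 percentage points on average, and in the latter it differed by -2.18. On chromosome 11 at positions 117900001 to 118000000, cover was 10.4%, 18.8% and 30.3% at D1, D3 and D5 of OySyNyK, against 3.18%, 6.23% and 7.41% with OSNK. With a score of at least 100, the differences there at D1 and D5 were 2.02 and 14.1 percentage points. On chromosome 12 at positions 103800001 to 103900000, OySyNyK was higher by 8.84, 11.4 and 9.46 percentage points, and by 1.03, 7.09 and 4.04 with a score of at least 100. The region from 140500001 to 140600000 on chromosome 4 reached 34.1% at OySyNyK D5 and 13.1% at OSNK D5, a difference of 8.77 points with a score of at least 100. On chromosome 17, the regions starting at 28300001 and 24700001 were higher by at least 8.06 and 8.00 points on every day. Their differences at D1, D3 and D5 were 5.38, 6.18 and 5.26 points and 6.07, 8.42 and 4.50 points with a score of at least 100. In the opposite direction, positions 52800001 to 52900000 on chromosome 2 were covered to 25.3%, 45.5% and 31.8% with OSNK and to 12.998%, 11.1% and 4.34% with OySyNyK, against 11.1% in MEF and 4.24% in iPSC. The difference there at D1 was -7.33 points instead of -12.3 with equal numbers of peaks. On chromosome 4, positions 53100001 to 53200000 reached 47.5% at OSNK D3 and were listed without any peak in iPSC. The other 3 such regions started at 75500001 on chromosome 17, 128000001 on chromosome 8 and 126300001 on chromosome 3. A score of at least 100 changed the D5 difference on chromosome 17 from -16.7 to -11.0 points and that on chromosome 8 from -17.8 to -6.57, and the latter was -9.45 with equal numbers of peaks.

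A large part of the peaks of each intermediate lay in neither end state. These intermediate-only peaks made up 52.2%, 55.2% and 58.8% of the OSNK lists at D1, D3 and D5 and 45.2%, 51.8% and 46.6% of the OySyNyK lists. Over 7 alternatives the OSNK shares were 39.0% to 56.4%, 50.1% to 63.5% and 53.7% to 64.1% on these days. The OySyNyK shares were 35.1% to 49.7%, 45.5% to 57.2% and 44.7% to 52.0%. The MEF and iPSC lists held fewer peaks than any intermediate list, and the effect of this on the shares was not separated. Part of the intermediate-only peaks was found in other intermediates. On the same day, 62.3%, 52.6% and 53.7% of those of OySyNyK at D1, D3 and D5 overlapped an OSNK peak, and 45.9%, 45.7% and 32.4% of those of OSNK overlapped an OySyNyK peak. Within a method, 60.5% of those at OSNK D3 overlapped a D1 peak and 61.2% of those at OSNK D5 a D3 peak, against 50.5% and 60.7% with OySyNyK. Of the 60659 at OSNK D1, 41.2% were overlapped at OSNK D5, and of the 45678 at OySyNyK D1, 32.0% were overlapped at OySyNyK D5.

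Chromosomes differed in their share of peaks. The X chromosome, 6.31% of the sequence spanned by peaks, held 0.777% of the MEF peaks (95% interval 0.711 to 0.847) and 0.193% of the iPSC peaks (0.158 to 0.233). The share went from 0.841% to 0.467% and 0.388% over the days of OSNK and from 0.628% to 0.355% and 0.320% over those of OySyNyK, alongside the falling median score. With equal numbers of peaks, X shares were 0.706% in MEF, 0.437%, 0.288% and 0.238% over the days of OSNK, 0.395%, 0.249% and 0.269% over those of OySyNyK and 0.193% in iPSC. With a score of at least 100, they were 0.516% in MEF, 0.474%, 0.222% and 0.173% with OSNK, 0.327%, 0.177% and 0.208% with OySyNyK and 0.170% in iPSC (95% interval 0.106 to 0.257), an interval that includes the values at D3 and D5 of both methods. In both of these settings OSNK D1 was below MEF and OySyNyK D5 above OySyNyK D3. In the 6 intermediates, the peak density of each autosome relative to MEF lay between 0.756 and 1.21 times that of the median autosome. In iPSC this ratio was 0.294 on chromosome 13, 0.299 on chromosome 16, 0.509 on chromosome 18, 0.584 on chromosome 6, 1.24 on chromosomes 5 and 11, 1.21 on chromosome 17 and 1.75 on chromosome 12. On chromosomes 13 and 16 it was 0.122 and 0.155 with a score of at least 100. On chromosomes 5, 6, 11 and 17 the ratio had moved towards the iPSC value over the days of both methods. With OySyNyK, chromosome 6 had 0.988, 0.888 and 0.756 at D1, D3 and D5. Chromosome 17 had 1.207 at OySyNyK D5 and 1.209 in iPSC. Chromosomes 13 and 16 had 0.884 and 0.915 at OySyNyK D5, far above their iPSC values. Chromosome 13 had 7.15 iPSC peaks per Mb, chromosome 16 had 6.52 and chromosome 12 had 36.6. Without chromosomes 12, 13, 16, 18 and X, the iPSC-gained differences between the methods were 3.54, 7.04 and 8.55 percentage points, and without chromosomes 5, 6, 11 and 17 as well they were 3.21, 6.62 and 8.04.

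**Figure D4:**
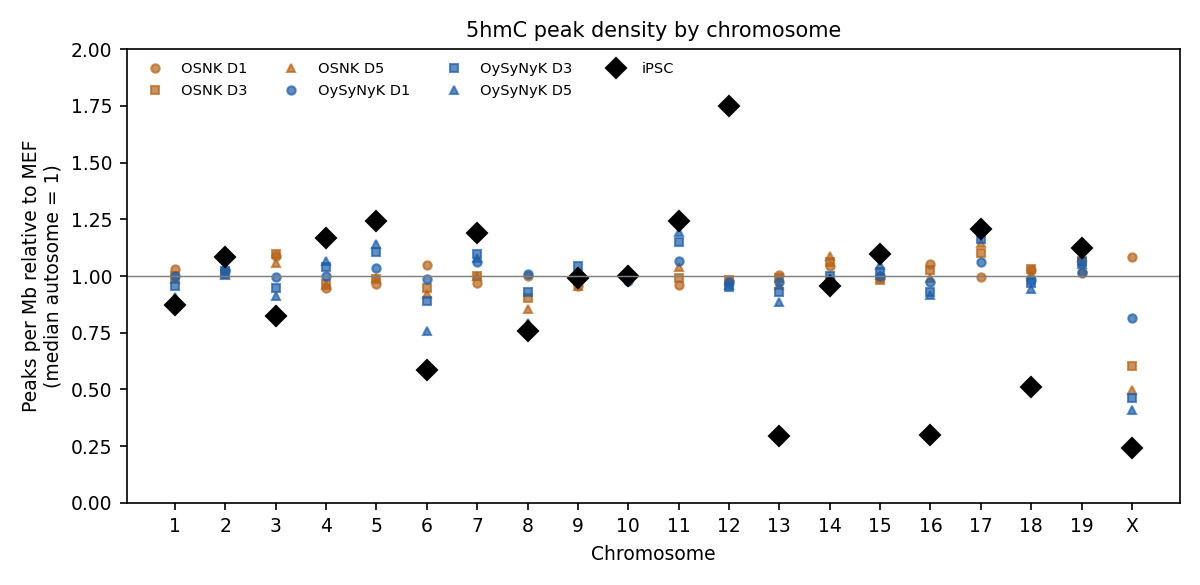
Peaks per Mb of each chromosome relative to MEF, divided by the value of the median autosome of the same library, for the 6 intermediates (coloured symbols by day) and iPSC (black diamonds). Autosomes of the intermediates lie between 0.756 and 1.21, while iPSC reaches 1.75 on chromosome 12 and 0.294 on chromosome 13.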

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

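Steps between days that went up with one method and down with the other are listed here; each rests on 1 library per day and method, and the difference was not tested. From D3 to D5 the number of peaks rose by 3265 with OSNK and fell by 23102 with OySyNyK. From D1 to D3 the covered length rose by 6.23 Mb with OSNK and fell by 2.58 Mb with OySyNyK. From D3 to D5 the median peak width fell by 261 bp with OSNK and rose by 23 bp with OySyNyK. OSNK D3, with a median width of 911 bp, takes part in all 3 of these contrasts.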

How the results depend on the processing

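The settings with 500-bp peaks and those without chromosomes were added after seeing the data, as were all alternatives for regions gained or lost in order, for X shares and for chromosome ratios. The OySyNyK minus OSNK difference over iPSC-gained peaks stayed above 0, interval included, in 24 of 24 alternative values (2.99 to 10.3 percentage points), and that over MEF-only peaks stayed below 0 in 23 of 24. The exception was D3 with 500-bp peaks, 0.0944. Its cause was not tested, although OSNK D3 has the widest peaks. With equal numbers of 500-bp peaks the MEF-only differences were small, at -0.745, -1.33 and -1.17 percentage points at D1, D3 and D5. Longer or wider OSNK lists would favour the direction of the MEF-only differences, and their part in them was not separated. The rise of iPSC-gained peaks and the fall of MEF-only peaks from D1 to D5 kept their direction in 14 of 14 values each (7.56 to 17.1 and -46.9 to -27.8). The change of shared peaks with OySyNyK from D1 to D5 turned to 0.252 with an overlap of at least 50% of the peak, 0.747 with equal numbers and 0.865 with equal numbers of 500-bp peaks. The iPSC overlap of OySyNyK-specific peaks ranged from 8.41% to 19.5% at D1, 11.6% to 24.5% at D3 and 21.8% to 32.0% at D5, and that of OSNK-specific peaks from 1.35% to 6.05%, 2.34% to 9.32% and 3.34% to 9.68%. Of 80 values for named regions, 62 stayed within 1.5 times the main value, 18 moved further and 0 changed sign; the lowest D1 difference was 1.03 on chromosome 12 (103800001), with a score of at least 100. The chromosome 13 ratio in iPSC ranged from 0.122 to 0.311, that of chromosome 16 from 0.155 to 0.318 and that of chromosome 12 from 1.66 to 2.15.

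For the MEF overlap, the differences between methods, the changes over days, the shared bases and the counts, values outside the main interval, or beyond 1.5 times a main value with no interval, were as follows; the cause was not tested. Of the other values, such as shares per library, 187 stayed within these bounds, 369 moved beyond them and 3 changed sign; they are not listed singly. In each sentence the order is iPSC peaks overlapped by MEF peaks (percent), then differences between methods over iPSC-gained and MEF-only peaks, then changes from D1 to D5. With an overlap of at least 50% of the peak, they were 19.5%, 5.35 at D3 for iPSC-gained, -6.50, -6.48 and -5.83 at D1, D3 and D5 for MEF-only, and changes of 16.6 for iPSC-gained with OySyNyK and -40.9 for MEF-only with OSNK. With a score of at least 100, they were 18.6%, 4.47, 7.44 and 9.27 for iPSC-gained, -8.56 and -5.49 at D1 and D3 for MEF-only, changes of 7.56 (OSNK) and 12.4 (OySyNyK) for iPSC-gained and of -46.9 and -45.5 for MEF-only. Peak numbers at that score were 33939 in MEF, 60909, 39719 and 32993 in OSNK, 47982, 36174 and 21636 in OySyNyK and 12974 in iPSC. With equal numbers of peaks, they were 18.7%, 3.97 and 10.3 at D3 and D5 for iPSC-gained, -1.58, -4.30 and -1.88 for MEF-only, changes of 9.96 and 17.1 for iPSC-gained and of -27.8 and -28.1 for MEF-only. With peaks within 1 kb merged, the MEF overlap was 22.6%, and no other of the values named at the start of this list moved. With 500-bp peaks, they were 17.6%, 8.63 at D3 for iPSC-gained, and -4.77 and -6.62 at D1 and D5 for MEF-only. With equal numbers of 500-bp peaks, they were 14.8%, 10.02 at D5 for iPSC-gained, -0.745, -1.33 and -1.17 for MEF-only, changes of 9.52 and 16.3 for iPSC-gained and of -28.2 and -28.6 for MEF-only, and 23.8% of bases shared between the methods at D3. Regions gained in order numbered 1608 (OSNK) and 2478 (OySyNyK) with a score of at least 100. Regions lost in order numbered 21501 and 19153 with that score, 22213 and 21176 with equal numbers of peaks and 22810 and 22270 with equal numbers of 500-bp peaks. Without chromosomes 12, 13, 16, 18 and X none of the values named at the start of this list moved beyond those bounds, and without 5, 6, 11 and 17 as well, run for differences between the methods, none of those did. The methods were paired by day in their differences, without a test over the 3 days, for which an exact sign-flip test cannot go below p = 0.25. With 1 library per group there was no replicate to leave out. The alternatives for gene features and gene lists were not run, because no annotation of the lists' assembly was used here. Depth, which was unknown, limits every count of peaks.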

Other observations

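In the weighing below, the tests of list length and width and of enrichment were chosen after the result was seen. So were the test without 9 chromosomes and the comparison of 10-Mb blocks with their median. The settings with 500-bp peaks or without chromosomes were added after seeing the data. Gains in iPSC were uneven along chromosomes. Among 10-Mb blocks with at least 20 MEF peaks, the median ratio of iPSC to MEF peaks was 0.638. The highest ratios were 2.62 in the block starting at 180000001 on chromosome 2, which held only 29 MEF peaks, and 2.54 in the block starting at 100000001 on chromosome 12. The next block of chromosome 12, starting at 110000001, had 2.02. Blocks starting at 20000001 and 50000001 on chromosome 7 had ratios of 2.02 and 1.93, and the block starting at 120000001 on chromosome 5 had 1.93. MEF peaks with an iPSC peak had a median score of 122, and MEF peaks without one had 100.2.

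OySyNyK libraries overlapped more iPSC-gained peaks than OSNK libraries on each of the 3 days. Longer or wider lists would favour OSNK, which covered more sequence on every day. Shifted OySyNyK peaks on average overlapped fewer iPSC-gained peaks than shifted OSNK peaks, with differences of -0.756 percentage points or lower. The 95% interval of -0.842 to -0.671 is that of a difference between means of 100 shifts, not the spread of single shifts. At D3 the SD over shifts was 0.282 for OSNK and 0.333 for OySyNyK. The direction follows from the covered sequence, so the shifts give only its size. At D3, where OySyNyK had more peaks, its excess was 3.97 with equal numbers. Chromosomes that stand apart in iPSC are argued against as the whole cause, since the smallest daily difference was 3.54 without chromosomes 12, 13, 16, 18 and X (95% interval 2.94 to 4.06) and 3.21 without these and 5, 6, 11 and 17, the other autosomes outside the range of the intermediates (2.61 to 3.82). Better enrichment of the OySyNyK libraries as the only difference would raise overlap with MEF-only peaks too. At D1 and D5 the highest of those differences over all settings was -0.745 (95% interval -1.39 to -0.16). At D3 it was 0.0944 with 500-bp peaks (95% interval -0.64 to 0.83). A faster loss of MEF-only peaks with OySyNyK could also lower these values, and the intervals hold no variation between libraries. They therefore cannot decide whether enrichment raised the overlap with iPSC-gained peaks, and this stays open on each day. Shared peaks were also overlapped more often with OySyNyK, by 3.49, 8.22 and 7.39 percentage points at D1, D3 and D5. The 100-kb cover of OySyNyK correlated more with MEF at D1, D3 and D5 by Pearson's r (0.91, 0.84 and 0.81 against 0.89, 0.81 and 0.78). By Spearman's rho this held except at D5 (0.78 against 0.79). A difference between the methods, variation between single cultures, and the fact that the iPSC sample's title carries the OySyNyK factors stay open as untested.

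Chromosomes 13 and 16 had few peaks in the iPSC library. A generally lower sensitivity of that library is argued against by an indirect comparison. Keeping only peaks with a score of at least 200 in the other 7 libraries left the peak density of these chromosomes at 0.748 or above, relative to all peaks and to the median autosome. The lowest values, 0.748 and 0.756, were both of OySyNyK D5, and the others lay between 0.848 and 1.02. The values of 0.294 and 0.299 for iPSC set all iPSC peaks over all MEF peaks, which is another measure. Over the 22 blocks of 10 Mb on these chromosomes, the iPSC to MEF ratio lay between 0.0764 and 0.417, against the median of 0.638 over all blocks. All 22 lay below that median, against 99 of 230 blocks on the other autosomes. Chromosomes 13 and 16 were taken up because of their low ratios, so this count largely restates them. Ratios as low also occurred on other autosomes, such as 0.175 in the block starting at 50000001 on chromosome 8. A single change along the whole of each chromosome is therefore not shown. As hypotheses, a copy number that differs in the iPSC line, a control library that differs from it in copy number, or loss of 5hmC on chromosomes 13 and 16 could each give the low ratios. The peak lists hold no read coverage that would separate them, and chromosome 12, at 1.75, moved the other way.

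iPSCs were kept on MEF feeder cells per the growth protocol, so MEF peaks that are also iPSC peaks could in part come from feeder DNA. The prediction was that, with feeders as the whole source, these peaks would behave at D5 like other MEF peaks of equal score and width. After matching on 10 score and 10 width classes, they were overlapped more often by 20.1 percentage points at OSNK D5 (95% interval 18.8 to 21.4) and by 34.3 at OySyNyK D5 (33.1 to 35.6). However, a MEF peak that is called again in a second library may be more reliable than its score shows. Such a peak would recur more often at D5 whatever its source. The matched differences therefore cannot tell feeders from other sources, and the feeder share stays open.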
